A study of Danio rerio with 28 samples.

How the data were processed

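Poly(A)-selected RNA of whole zebrafish embryos was sequenced in 20 libraries and rRNA-depleted RNA in 8 libraries, as pairs of 125 bp reads. The deposited files hold counts, the number of reads per Ensembl gene, which per the submitters' processing notes come from TopHat2 2.1.1 and HTSeq 0.6.0. The genome build and annotation release are not given in the sources used here, so no gene positions are reported. The values were whole numbers with a different total in each library. The files hold 33737 gene identifiers, of which 21939 have a symbol in the reference table, and symbols are printed as that table gives them. Of the 28 files 14 end with HTSeq's summary lines. In these, reads outside annotated genes were 7.22% to 18.5% of the total for the poly(A) libraries (ybx1 MO) and 8.08% to 17.9% for the rRNA-depleted libraries. The summary lines were left out of all totals. Spike-in counts were not used here.

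The libraries were grouped by their labels into 14 groups of 2, and the libraries titled MO alone were taken as ybx1 MO from the series description. The design, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. Replicates share only a number between groups, so no pairing was assumed.

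The poly(A) and the rRNA-depleted libraries were analysed apart, in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (22377 and 21525 genes), scaled by trimmed mean of M values and tested with edgeR's robust quasi-likelihood test, with 10 and 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Comparisons were made between successive WT stages, between each knockdown and WT of the same hour, between the knockdowns, between amanitin stages, and between WT and amanitin at 4 hpf. The change of a knockdown effect between stages was tested as an interaction. A gene with a group at or under 3 counts over the group gives a fold change that depends on the prior count, and such genes are not named.

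Classes came from the rRNA-depleted libraries alone. The transcription-dependent class (called and at least 2-fold higher in WT than in amanitin at 4 hpf) had no CPM minimum. The maternal declining and maternal stable (within 0.5 on the log2 scale) classes needed at least 1 CPM in amanitin at 2 hpf. The scaling makes both relative to the typical mRNA, with a median change of 0 over all genes from 2 to 6 hpf in amanitin. Stable therefore does not mean that the amount of an mRNA was kept. Classes and 22 gene lists (501 symbols, 347 matched) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. The list of ribosomal protein genes was drawn by symbol and also took in RPS6KL1, a kinase-like gene, so its 74 tested members are not all ribosomal proteins. With the estimated correlation no class or list of any comparison passed 0.05.

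The text may name ybx1 and pabpc1a in each comparison, the 5 genes with the largest and the 5 with the lowest log2 fold change among called genes with a symbol, libraries that do not overlap and at least 10 CPM in the higher group, and up to 3 called members of each list by adjusted p. For interactions it may name 3 each way. Of the genes this rule gave, those printed were chosen after their values were seen, mainly among those whose call held under the alternatives.

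The tests were tried on simulated data with known changes for 2 comparisons. The depth was that of the libraries, and the spread of each gene was the one estimated from all libraries of the kit. Each gene thus had the same spread in every group, while the real poly(A) pairs had from 1209 to 5203 genes at least 2-fold apart. The trial cannot show the error rate with pairs that differ in spread. For ybx1 MO against WT at 6 hpf, edgeR recovered 5.97% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 81.8% of those changed 4-fold, and called 7 of 21665 unchanged genes. For amanitin at 6 against 4 hpf it recovered 76.1%, 89.6% and 98.5%, and called 12 of 20634. DESeq2 recovered 22.4%, 65.7% and 90.9% in the first, calling 43, and 76.1%, 86.6% and 98.5% in the other, calling 10. Camera called sets of 100 genes shifted by 0.3 (p = 8.22e-14 and 3.74e-50 on simulated data, a test across genes with a preset correlation) and 0 of 100 unshifted sets in each. The simulated genes were drawn independently of each other, so this trial cannot show how camera behaves with correlated genes.

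The overlap of the knockdowns was set against 20 simulations of unchanged groups. In each, WT and both knockdowns were drawn anew around the WT mean, and both knockdowns were compared with the same drawn WT libraries. The spread of each gene was the one estimated from all poly(A) libraries. Alternatives were DESeq2 1.42.0, median-of-ratios size factors, other filters and thresholds, a replicate block, a fit of only the groups compared, and leaving out each library in turn. Refits without every gene over 1% of a library, without 3 doubted libraries, and with interpolated WT controls were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.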

Results

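RNA was sequenced from whole zebrafish embryos of the AB strain between fertilisation and 6 hours post fertilisation (hpf), the span in which the embryo passes from RNA stored in the egg to transcription of its own genome. The 20 poly(A)-selected libraries formed 10 groups of 2: wild type (WT) at 0, 2, 3, 4 and 6 hpf, embryos injected with a morpholino against ybx1 (ybx1 MO) at 3, 4 and 6 hpf, and embryos injected with a morpholino against pabpc1a (pabpc1a MO) at 4 and 6 hpf. The 8 rRNA-depleted libraries formed 4 groups of 2: embryos given 0.2 ng of alpha-amanitin, which blocks RNA polymerase II, at 2, 4 and 6 hpf, and WT at 4 hpf. YBX1 encodes a cold shock domain protein that binds mRNA, and pabpc1a encodes a poly(A)-binding protein. The poly(A) libraries held 48204100 to 100000375 counted reads, and the rRNA-depleted libraries 39882963 to 66381933. A single gene without a symbol took 22.2% to 46.1% of the counts of each poly(A) library. Values are counts scaled to library size (CPM) as mean ± SD with n = 2, or log2 fold changes. Adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and they measure only the spread between these samples, of which the amanitin pairs alone are stated to be biological replicates.

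Embryos with blocked transcription were compared with WT embryos at 4 hpf to find which mRNAs depend on transcription. The WT embryos held mRNAs of early embryonic regulators that the amanitin embryos had in small amounts. They included sox19a, a SoxB1 gene, at 137 ± 0.936 against 1.35 ± 0.0650 CPM, and tbx16, a T-box gene of the mesoderm, at 312 ± 0.561 against 0.496 ± 0.109 CPM. The epithelial keratin gene krt18a.1 and the yolk layer apolipoprotein gene apoeb were also higher in WT, by 9.20 and 7.69 on the log2 scale (edgeR adjusted p = 3.74e-26 and 3.63e-26). Some egg mRNAs went the other way. TDRD6, BTG4 and DAZL, which act in germ cells, in deadenylation and in germ cell translation, were lower in WT by log2 fold changes of -1.42, -1.18 and -1.01 (edgeR adjusted p = 1.5e-18, 2.3e-16 and 4.5e-16). Both YBX1 (1.08) and pabpc1a (0.73) were higher in WT (edgeR adjusted p = 7.8e-17 and 1.0e-12).

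At an edgeR adjusted p under 0.05, 14830 of 21525 tested genes differed between WT and amanitin at 4 hpf, 7802 higher and 7028 lower in WT. Reads outside genes were 17.9% and 17.2% in the WT libraries against 9.18% and 9.02% in amanitin. Of the list of early zygotic transcripts 19 of 23 were higher in WT and 0 lower, with the same 19 and 0 when adjusted over the list alone (camera adjusted p = 9.8e-10; adjusted p = 0.0695 with an estimated correlation). The lists for Nodal signalling (17 higher, 1 lower), enveloping layer epithelium (17 and 1), yolk syncytial layer (10 and 0), dorsal organizer (10 and 1) and FGF signalling (8 and 1) shifted the same way, with the same counts adjusted over the list alone (adjusted p from 0.0695 to 0.0955 with an estimated correlation). The 4670 genes at least 2-fold higher in WT were taken as the transcription-dependent class, of which 4200 could be tested in the poly(A) libraries. The 3970 maternal declining genes and the 3765 maternal stable genes were defined from the amanitin time course in the same way.

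In the amanitin embryos mRNA levels were followed from 2 to 6 hpf. Between 2 and 4 hpf the oocyte kinase mRNA MOS fell from 196 ± 7.06 to 84.0 ± 3.37 CPM, and TOP2A, ca15b and BTG4 had log2 fold changes of -0.84, -0.78 and -0.61 (edgeR adjusted p = 2.4e-13, 1.6e-12 and 1.4e-10). Between 4 and 6 hpf BTG4 fell by 2.70, GMNN by 2.63 and CCNB1 by 1.84 on the log2 scale, genes for a deadenylation factor, a replication inhibitor and a mitotic cyclin. The share of ribosomal protein mRNAs grew in the same interval, with RPL12 going from 324 ± 0.0191 to 1326 ± 3.10 CPM, and MT-ND3, encoded by the mitochondrial genome, from 45.4 ± 1.62 to 278 ± 10.9 CPM. Both pabpc1a (1.51) and YBX1 (1.18) were higher at 6 than at 4 hpf (edgeR adjusted p = 2.1e-18 and 5.4e-18).

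Some zygotic mRNAs appeared in small amounts in spite of amanitin. The zinc finger gene klf17 reached 3.12 ± 0.0575 CPM at 4 hpf against 0.115 ± 0.0620 at 2 hpf (log2 fold change 4.73, edgeR adjusted p = 2.4e-13), where WT at 4 hpf held 105 ± 5.05 CPM. By 6 hpf klf17 fell to 0.0635 ± 0.0159 CPM. Of the early zygotic list, 16 of 23 were higher and 2 lower at 4 than at 2 hpf (16 and 3 adjusted over the list alone; camera adjusted p = 8.7e-05; adjusted p = 0.256 with an estimated correlation). Of the same list 17 were lower and 0 higher at 6 than at 4 hpf (camera adjusted p = 0.0044; adjusted p = 0.264 with an estimated correlation).

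Between 2 and 4 hpf 6954 genes differed in the amanitin embryos (3354 higher, 3600 lower), between 4 and 6 hpf 14570 (7124 and 7446), and between 2 and 6 hpf 15061 (7506 and 7555), by edgeR. Of 73 ribosomal protein genes, 67 were higher and 3 lower at 6 than at 4 hpf (camera adjusted p = 2.9e-16; adjusted p = 0.264 with an estimated correlation). All 13 mitochondrially encoded genes were higher (camera adjusted p = 1.8e-05; adjusted p = 0.264 with an estimated correlation). Of the list of deadenylation and poly(A) binding genes, 18 of 25 were higher and 7 lower (camera adjusted p = 0.0221; adjusted p = 0.447 with an estimated correlation). The amanitin libraries at 6 hpf differed in make-up from those at 4 hpf. Reads outside genes were 16.1% and 16.0% against 9.18% and 9.02%. All these values are shares of the counts of each library and were not scaled by spike-ins.

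**Figure D1:**
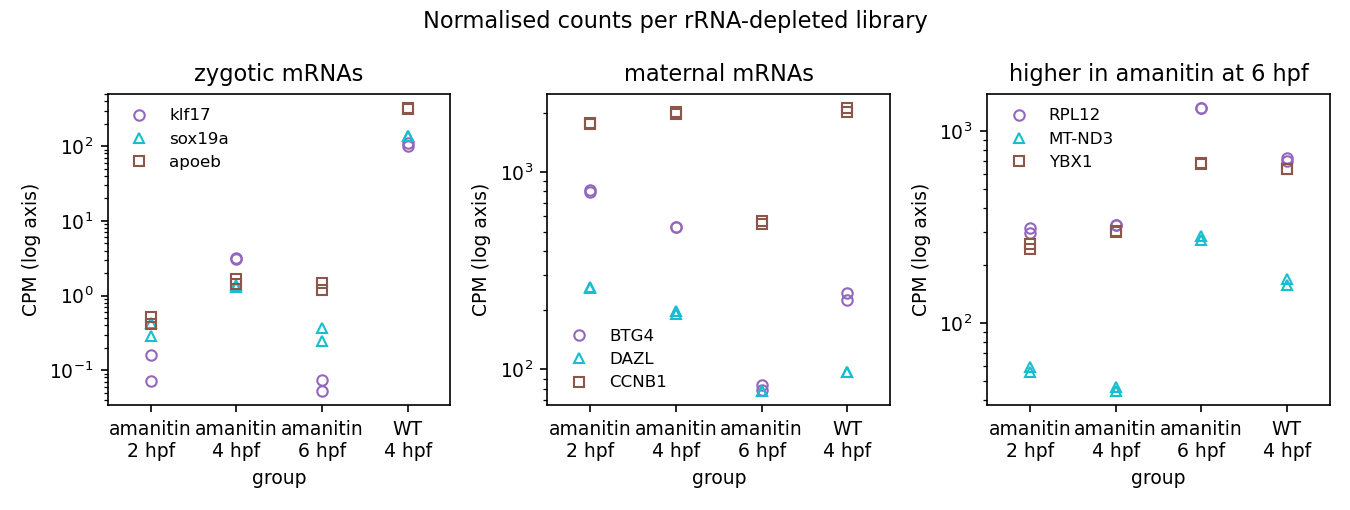
Normalised counts (CPM, log axis) of 9 mRNAs in each of the 8 rRNA-depleted libraries, 1 point per library, with groups on the horizontal axis. klf17 lies near 3.12 CPM in amanitin at 4 hpf and near 105 CPM in WT, and BTG4 falls from 528 CPM at 4 hpf to 81.3 CPM at 6 hpf in amanitin.

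The WT poly(A) libraries show the time course of the mRNAs that carry a poly(A) tail. Between fertilisation and 2 hpf, before most of the genome is transcribed, many mRNAs already changed in these libraries. Poly(A) selection also responds to tail length, which was not measured, so these values can change without a change in mRNA amount. CTCF, a gene for a chromatin insulator protein, went from 18.1 ± 1.07 to 214 ± 3.29 CPM, and sox19b, a SoxB1 regulator of genome activation, from 96.5 ± 0.918 to 434 ± 30.3 CPM. The receptor gene RYK and the m6A reader gene YTHDF3 were higher by 3.78 and 2.75 on the log2 scale. Oocyte and cell division mRNAs went down, among them ZAR1L (-2.98), TOP2A (-2.83), DAZL (-2.23), CCNB1 (-1.25) and the checkpoint gene BUB3 (-4.03), and so did PAN3, a deadenylase subunit gene (-2.19). YBX1 (-0.85) and pabpc1a (-1.32) were lower as well (edgeR adjusted p = 0.0012 and 3.8e-06).

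By edgeR 7681 of 22377 genes differed between 0 and 2 hpf, 3928 higher and 3753 lower. Of 74 ribosomal protein genes, 68 were lower and 1 higher (70 and 1 adjusted over the list alone; RPL31 at -1.34), and all 13 mitochondrially encoded genes were lower, MT-ND5 by a log2 fold change of -1.56 (camera adjusted p = 3.4e-26 and 1.1e-11; adjusted p = 0.426 and 0.122 with an estimated correlation). Of the oocyte list 14 of 26 were lower and 4 higher (15 and 4 adjusted over the list alone), and of the cell cycle list 15 of 32 were lower and 6 higher (17 and 7 adjusted over the list alone; camera adjusted p = 0.0033; adjusted p = 0.412 with an estimated correlation).

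At 3 hpf the early zygotic regulators appeared in WT. klf17 went from 0.583 ± 0.0703 to 58.5 ± 26.3 CPM, and the homeobox gene irx7 from 0.156 ± 0.0436 to 23.2 ± 6.43 CPM. The epidermal regulator grhl3 was higher by 7.53, the FGF feedback phosphatase DUSP6 by 8.25, SOX3 by 5.47 and the Nodal antagonist lft1 by 3.82 on the log2 scale (edgeR adjusted p = 0.00058, 0.0005, 0.00036 and 0.00056). MOS and DAZL continued down, at -1.13 and -1.08.

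Of 22377 genes, 1026 differed between 2 and 3 hpf (734 higher, 292 lower, edgeR), with 183, 217 and 250 when WT 2 hpf replicate 1, WT 2 hpf replicate 2 or WT 3 hpf replicate 2 was left out. DESeq2 called 1997, and edgeR with only these 4 libraries 4562. Of 23 early zygotic transcripts 14 were higher and 0 lower (17 and 1 adjusted over the list alone; camera adjusted p = 9.3e-11; adjusted p = 0.346 with an estimated correlation), and 7 were higher without WT 2 hpf replicate 1. The transcription-dependent class had a median log2 fold change of 0.35, or 0.30 with groups at or under 3 counts set to 3 counts, with 368 genes higher and 33 lower (camera adjusted p = 8.0e-04; adjusted p = 0.549 with an estimated correlation).

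By 4 hpf mRNAs of the first tissues were present in WT. The enveloping layer, the outer epithelium of the early embryo, contributed krt8 at 190 ± 166 against 2.91 ± 0.511 CPM and the protease gene CAPN9 at 8.62 on the log2 scale. Regulators of mesendoderm and of the dorsal side, mixl1 (4.19) and GSC (2.76), the ventral signal bmp7a (6.07), the yolk layer and endoderm regulator HNF4A (6.99) and foxo3b (3.35) were all higher. Some egg mRNAs went down further, with MOS at -1.28, the germ plasm organiser buc at -1.15 and the zinc finger gene cth1 at -1.06 (edgeR adjusted p = 7.5e-05, 0.00079 and 5.1e-05).

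Of 22377 genes, 6161 differed between 3 and 4 hpf (3821 higher, 2340 lower, edgeR), with 2826 without WT 3 hpf replicate 1 and 3434 without WT 4 hpf replicate 1. A fit of only these 4 libraries called 0 genes by edgeR, with 5035 at an unadjusted p under 0.05, so the calls rest on the spread shared by all poly(A) libraries. DESeq2 with all poly(A) libraries called 6813. Genes of the transcription-dependent class had a median of 2.40, or 2.24 with groups at or under 3 counts set to 3 counts, with 2542 genes higher and 16 lower (camera adjusted p = 6.5e-52; adjusted p = 0.0605 with an estimated correlation). Enveloping layer genes (15 of 21 higher, 0 lower), Nodal signalling genes (15 of 20 and 0), yolk syncytial layer genes (8 of 11 and 0) and FGF signalling genes (8 of 9 higher, 1 lower) moved with them. In this order the numbers were 15 and 1, 15 and 0, 9 and 0, 8 and 1 adjusted over the list alone (camera adjusted p = 8e-06, 1.1e-07, 6e-05 and 0.00319; adjusted p = 0.234, 0.17, 0.17 and 0.178 with an estimated correlation). Without WT 3 hpf replicate 1 they were 10, 11, 4 and 4 higher. Of 26 oocyte mRNAs 11 were lower and 2 higher (12 and 4 adjusted over the list alone; camera adjusted p = 0.000481; adjusted p = 0.17 with an estimated correlation). Ribosomal protein mRNAs turned upward, 72 of 74 being higher (also 72 adjusted over the list alone; RPL7 at 0.97; camera adjusted p = 5.8e-24; adjusted p = 0.17 with an estimated correlation), and 52 without WT 4 hpf replicate 1. The 2 WT libraries at 4 hpf stood apart, with 5203 genes at least 2-fold apart between them against 1209 to 3571 in the other poly(A) pairs.

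At 6 hpf, when gastrulation starts, WT embryos held the regulators of the germ layers and of the body axis. The neural gene SOX2 was at 86.0 ± 5.77 against 0.389 ± 0.370 CPM and the posterior gene cdx4 at 192 ± 1.70 against 0.535 ± 0.0620 CPM. FOXA2 (5.18), the secreted Wnt inhibitor frzb (5.21), the adhesion gene CDH2 (4.01) and the apolipoprotein gene apoa1a of the yolk syncytial layer (9.08) were higher. Maternal regulators had fallen, CCNA1 from 621 ± 3.12 to 75.7 ± 4.27 CPM, nanog from 950 ± 78.3 to 87.1 ± 7.77 CPM and buc from 224 ± 95.5 to 11.1 ± 1.33 CPM. GMNN, whose protein restrains replication, was lower by a log2 fold change of -1.67. YBX1 rose from 605 ± 220 to 2209 ± 225 CPM and pabpc1a from 745 ± 167 to 1661 ± 437 CPM (edgeR adjusted p = 2.6e-07 and 6.2e-06).

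The change from 4 to 6 hpf took in 13355 of 22377 genes (6233 higher, 7122 lower, edgeR). Median-of-ratios scaling moved the median of all genes from -0.06 to 0.22, and changes of that size have no fixed sign here. Ribosomal protein genes (71 of 74 higher, 0 lower, median 1.91; RPL31 at 2.07) and mitochondrially encoded genes (13 of 13 higher; MT-ND3 at 1.68) were above that shift (camera adjusted p = 2.7e-29 and 7.6e-05; adjusted p = 0.22 and 0.22 with an estimated correlation). BMP signalling genes were higher in 10 of 11 (11 adjusted over the list alone) and Wnt signalling genes in 7 of 10 with 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.0036; adjusted p = 0.156 with an estimated correlation). Of 13 epiboly genes for adhesion and the cytoskeleton 9 were higher and 2 lower (camera adjusted p = 0.0101; adjusted p = 0.22 with an estimated correlation). The maternal declining class, defined with amanitin, was lower here by a median of -0.58 and the maternal stable class by a median of -0.65. The class names thus refer to the amanitin course only, and there they are relative to the typical mRNA. Over 13447 maternal genes the changes from 4 to 6 hpf in amanitin and in WT had Pearson's r = 0.0856, with 53.8% of the same sign, and genes are not independent replicates. Of the oocyte list 20 of 26 were lower and 2 higher (20 and 3 adjusted over the list alone), at a median of -2.24 (camera adjusted p = 2.8e-06; adjusted p = 0.156 with an estimated correlation).

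**Figure D2:**
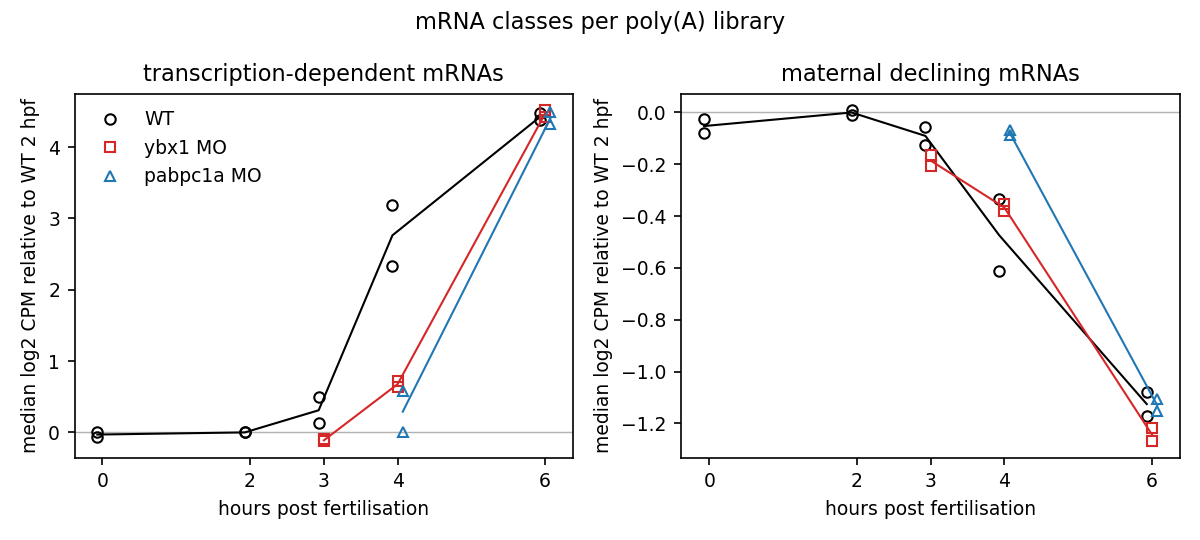
Median log2 CPM relative to WT at 2 hpf of 4200 transcription-dependent and 3970 maternal declining genes in each poly(A) library, 1 point per library with lines through the group means, against hours post fertilisation. At 4 hpf the WT libraries lie at 3.19 and 2.34 for the transcription-dependent genes, the ybx1 MO libraries at 0.64 and 0.72 and the pabpc1a MO libraries at 0.00 and 0.58.

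The series compares the knockdowns with WT to ask how each protein affects the mRNA content of the embryo. The target mRNAs come first. In the libraries labelled ybx1 MO, YBX1 was at 375 and 373 CPM at 3 hpf against 238 and 316 in WT, at 434 and 456 at 4 hpf against 761 and 449, and at 2611 and 2602 at 6 hpf against 2050 and 2368. The log2 fold changes of 0.43, -0.44 and 0.24 were not called (edgeR adjusted p = 0.115, 0.0662 and 0.346), although YBX1 at 4 hpf was called at -0.77 without WT 4 hpf replicate 2 (edgeR adjusted p = 0.00012) and stood at -0.01 without replicate 1. In the libraries labelled pabpc1a MO, pabpc1a was at 484 and 510 CPM at 4 hpf against 864 and 627 in WT, and at 1501 and 1391 at 6 hpf against 1352 and 1970. It was lower at 4 hpf (-0.58, edgeR adjusted p = 0.0074) but not called without WT 4 hpf replicate 1 (-0.29, edgeR adjusted p = 0.15) or without pabpc1a MO 4 hpf replicate 1 (-0.54, edgeR adjusted p = 0.0597). At 6 hpf it was not called (-0.20, edgeR adjusted p = 0.46, and 0.09 without WT 6 hpf replicate 2). A morpholino can block translation and leave the mRNA in place, so the mRNA level does not check these labels. No control morpholino is named, and each knockdown was compared with WT.

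At 3 hpf the ybx1 MO embryos lacked most of the early zygotic mRNAs that WT embryos had gained. klf17 was at 1.74 ± 0.330 against 58.5 ± 26.3 CPM and irx7 at 0.276 ± 0.0643 against 23.2 ± 6.43 CPM. The SoxB1 genes SOX3 (-5.74) and sox19a (-7.36), grhl3 (-6.94) and lft1 (-3.36) were lower as well (edgeR adjusted p = 9.0e-05, 0.00079, 0.00024 and 0.00035). Some egg mRNAs were higher than in WT, with MOS at 86.5 ± 5.62 against 40.7 ± 6.98 CPM and DAZL at 74.5 ± 3.25 against 39.1 ± 4.37 CPM, and the cyclin mRNA CCNB1 at 0.76. IGF2BP3 and YTHDF2, both readers of RNA modifications, were lower (-0.92 and -0.91, edgeR adjusted p = 3.2e-05 and 0.0011).

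Of 22377 genes, 3311 differed (1020 higher, 2291 lower, edgeR), and 1911, 1431, 1134 and 1036 when WT replicate 1, WT replicate 2, ybx1 MO replicate 1 or ybx1 MO replicate 2 was left out. A fit of only these 4 libraries called 7251. The higher share of 30.8% became 41.3% with median-of-ratios scaling and 47.5% without the genes over 1% of a library. The transcription-dependent class had a median of -0.96, or -0.51 with groups at or under 3 counts set to 3 counts, with 66 genes higher and 799 lower (camera adjusted p = 2.2e-05; adjusted p = 0.789 with an estimated correlation). Of 23 early zygotic transcripts 17 were lower and 0 higher (19 and 0 adjusted over the list alone; camera adjusted p = 1.3e-07; adjusted p = 0.75 with an estimated correlation), 10 without ybx1 MO replicate 2. Of 26 oocyte mRNAs 6 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.00469; adjusted p = 0.75 with an estimated correlation), with 2 higher without WT replicate 2 or ybx1 MO replicate 2. Germ plasm genes were higher in 7 of 15 and lower in 0 (8 and 0 adjusted over the list alone; camera adjusted p = 3.8e-06; adjusted p = 0.75 with an estimated correlation), 2 without ybx1 MO replicate 2. Ribosomal protein genes went both ways, 12 higher and 4 lower (14 and 7 adjusted over the list alone), with RPL21 at -1.11, and 0 higher and 2 lower without WT 3 hpf replicate 2. Their camera adjusted p of 0.0412 became 0.139 without WT 3 hpf replicate 2 (adjusted p = 0.906 with an estimated correlation).

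At 4 hpf the first tissue mRNAs were low in ybx1 MO embryos. krt8 was at 6.85 ± 0.318 against 190 ± 166 CPM, CAPN9 at -6.70, mixl1 at -3.75, GSC at -2.75 and HNF4A at -6.26 on the log2 scale (edgeR adjusted p = 0.00014, 0.00023, 1.3e-05, 0.00045 and 0.00021). The egg mRNAs MOS (1.27) and CCNB1 (0.92) were still higher than in WT. The mitotic kinase mRNAs AURKB and aurka were lower, at 14.9 ± 1.41 against 59.9 ± 11.6 CPM and 49.1 ± 2.04 against 123 ± 1.78 CPM. The cell cycle list of 32 genes that holds them had a median of 0.18. The p53 pathway gene PHLDA3 (-3.74), foxo3b (-2.45) and the stress regulator atf4b (-3.79) were lower, while the chaperone mRNA HSP90B1 (0.88) and the RNA methyltransferase mRNA NSUN2 (0.93) were higher (edgeR adjusted p = 2.9e-05 and 0.0013).

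Of 22377 genes, 7207 differed at 4 hpf (2869 higher, 4338 lower, edgeR), 4020, 3852 and 4687 without WT 4 hpf replicate 1, ybx1 MO replicate 1 or ybx1 MO replicate 2, and 1009 (109 higher, 900 lower) in a fit of only these 4 libraries. The median of the transcription-dependent class was -1.99, or -1.92 with groups at or under 3 counts set to 3 counts, with 46 genes higher and 2261 lower (camera adjusted p = 7.1e-32; adjusted p = 0.295 with an estimated correlation). Enveloping layer genes were lower in 15 of 21 and higher in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 1.2e-04; adjusted p = 0.415 with an estimated correlation), and 5 were lower without ybx1 MO replicate 1. Nodal signalling genes were lower in 14 of 20 and higher in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 1.5e-05; adjusted p = 0.411 with an estimated correlation), and 7 were lower without ybx1 MO replicate 1. Of 74 ribosomal protein genes 46 were lower and 0 higher (53 and 0 adjusted over the list alone; median -0.58; RPL21 at -1.65; camera adjusted p = 2.4e-10; adjusted p = 0.454 with an estimated correlation), and 24 were lower without WT 4 hpf replicate 1. Of 15 p53 pathway genes 7 were lower and 0 higher (camera adjusted p = 0.0031; adjusted p = 0.321 with an estimated correlation). Of 15 germ plasm genes 9 were higher and 0 lower (camera adjusted p = 1.2e-04; adjusted p = 0.324 with an estimated correlation), or 5 without WT 4 hpf replicate 1.

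**Figure D3:**
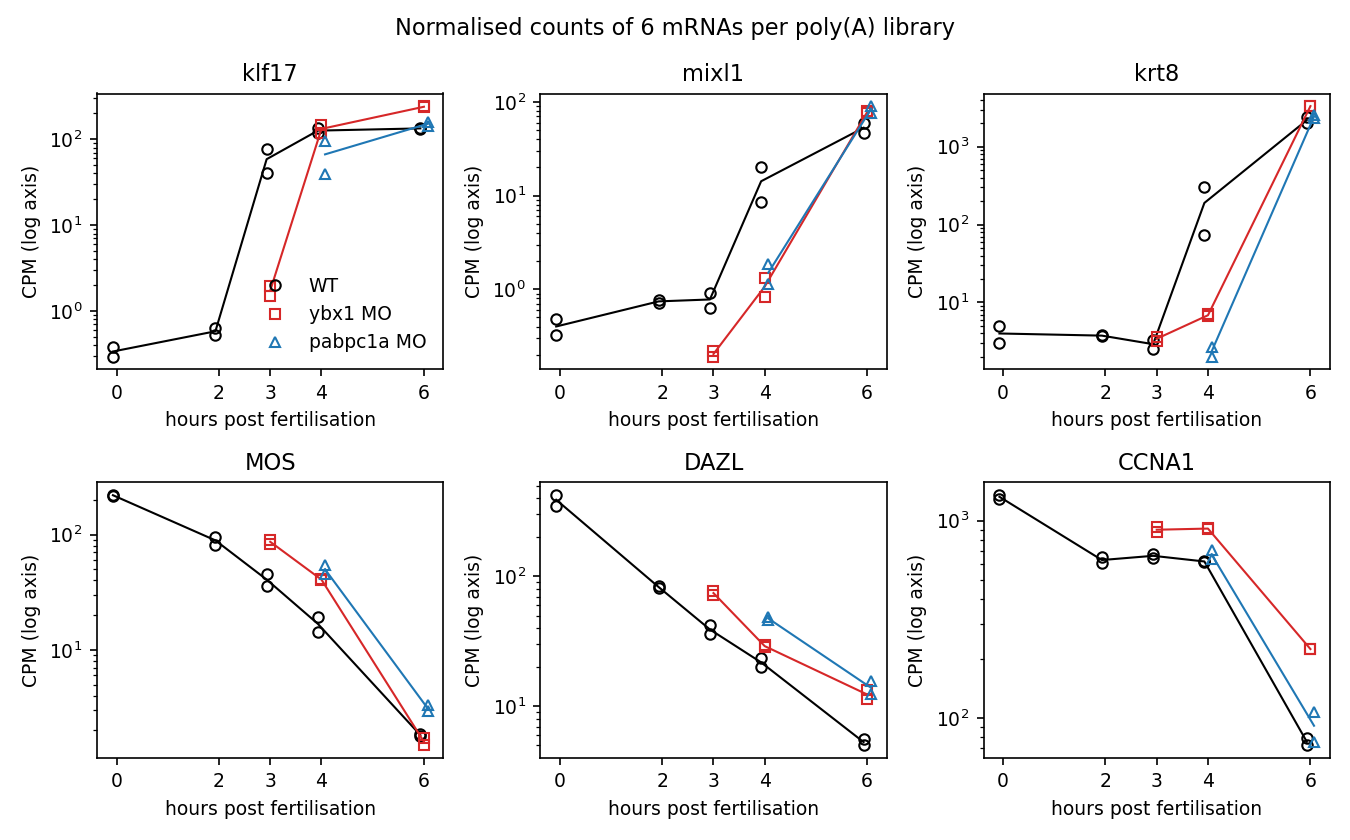
Normalised counts (CPM, log axis) of 6 mRNAs in each poly(A) library against hours post fertilisation, 1 point per library with lines through the group means. At 4 hpf krt8 is at 190 CPM in WT, 6.85 CPM in ybx1 MO and 2.34 CPM in pabpc1a MO, and MOS at 16.8, 40.6 and 49.9 CPM.

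At 6 hpf the median of the transcription-dependent class in the ybx1 MO embryos was near the WT level, while single mRNAs inside and outside this class differed. The apolipoprotein mRNA apoa1a was at 1.05 ± 0.0878 against 27.5 ± 8.62 CPM, apobb.1 at -6.70 and apoc2 at -5.41, while the related APOB was higher at 80.7 ± 3.70 against 2.79 ± 1.29 CPM (edgeR adjusted p = 1.3e-06, 5.5e-07, 0.0009 and 0.00043). Some maternal mRNAs were higher than in WT, with CCNA1 at 223 ± 0.103 against 75.7 ± 4.27 CPM, DAZL at 1.21, nanog at 1.09, cth1 at 1.01 and the Nodal pathway factor foxh1 at 0.73. Regulators of patterning moved apart, with the organizer gene lhx1a higher (1.91) and FOXA2 (-1.91), the ventral gene msx1b (-2.32), cdx4 (-1.19) and the neural gene neurog1 (-3.09) lower. HSP90B1 (0.81), the rRNA methyltransferase gene NSUN5 (1.32) and the RNA surveillance gene UPF1 (0.72) were higher, and the stress response gene HERPUD1 (-0.85) and the poly(A)-binding protein gene PABPC1L (-0.84) lower (edgeR adjusted p = 4.8e-05, 1.1e-05, 0.00012, 0.00022 and 0.00024).

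Of 22377 genes, 6150 differed at 6 hpf (2658 higher, 3492 lower, edgeR), 3427 and 3452 without ybx1 MO replicate 1 or 2. Both ybx1 MO libraries at 6 hpf stood apart in make-up. Genes that pass 1% in at least 1 library, other than the top gene, took 7.10% and 7.28% of their counts, against 1.19% and 1.34% in WT at 6 hpf, and reads outside genes were 18.3% and 18.5%, against 7.22% to 9.77% in the other ybx1 MO libraries. Maternal mRNAs did not pass the test as a group. The maternal declining class had a median of -0.11 with 567 genes higher and 773 lower (camera adjusted p = 0.939; adjusted p = 0.98 with an estimated correlation), and of 26 oocyte mRNAs 9 were higher and 5 lower (9 and 6 adjusted over the list alone; camera adjusted p = 0.272; adjusted p = 0.98 with an estimated correlation), with 4 higher without ybx1 MO replicate 1 or WT 6 hpf replicate 2. The transcription-dependent class had a median of -0.04 and a mean of -0.13, where camera gave the direction as up (265 genes higher and 446 lower by edgeR, camera adjusted p = 0.961; adjusted p = 0.98 with an estimated correlation). Of 20 Nodal signalling genes 5 were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.0102; adjusted p = 0.98 with an estimated correlation). Of 11 yolk syncytial layer genes 2 were lower and 0 higher, with a median of 0.13 and a mean of -1.01 (camera adjusted p = 0.695; adjusted p = 0.98 with an estimated correlation). Ribosomal protein genes had 4 higher and 1 lower (1 and 0 adjusted over the list alone; median 0.21; camera adjusted p = 3.1e-04; adjusted p = 0.98 with an estimated correlation), with 1 higher without ybx1 MO replicate 1 or 2.

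At 4 hpf the pabpc1a MO embryos also had little of the first tissue mRNAs. krt8 was at 2.34 ± 0.467 against 190 ± 166 CPM, CAPN9 at -7.99, mixl1 at -3.24, HNF4A at -6.53, foxo3b at -3.56 and PHLDA3 at -4.91 (edgeR adjusted p = 4.1e-05, 0.00013, 3.3e-05, 0.00015, 3.2e-05 and 8.8e-05). Some egg mRNAs stood above WT, with MOS at 49.9 ± 5.80 against 16.8 ± 3.71 CPM, ZAR1L at 1.45, ca15b at 1.13 and DAZL at 1.12 on the log2 scale. BTG4 and CNOT7, parts of the machinery that shortens poly(A) tails, were higher at 1.97 and 1.66, while the list of 25 deadenylation and poly(A) binding genes had a median of 0.123. RPL29 stood out among the ribosomal protein mRNAs with 10.6 ± 1.84 against 91.6 ± 12.7 CPM, and RPS15 was at -1.14 (edgeR adjusted p = 2.2e-09 and 5.3e-05).

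Of 22377 genes, 7683 differed (3018 higher, 4665 lower, edgeR), 4765 without WT 4 hpf replicate 1 and 4248 without pabpc1a MO replicate 1. A fit of only these 4 libraries called 0 genes by edgeR, with 5949 at an unadjusted p under 0.05. DESeq2 with all poly(A) libraries called 8339. In pabpc1a MO 4 hpf replicate 1, genes that pass 1% in at least 1 library, other than the top gene, took 5.62% of the counts. They took 1.56% in replicate 2 and 0.992% and 0.709% in WT at 4 hpf. For the transcription-dependent class the median was -2.36, or -2.23 with groups at or under 3 counts set to 3 counts, with 53 genes higher and 2570 lower (camera adjusted p = 1.5e-38; adjusted p = 0.0806 with an estimated correlation). The maternal declining class lay above WT, with a median of 0.38, 1332 genes higher and 354 lower (camera adjusted p = 4.4e-14; adjusted p = 0.0806 with an estimated correlation). Of 26 oocyte mRNAs 14 were higher and 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 7.7e-07; adjusted p = 0.0806 with an estimated correlation). Enveloping layer genes were lower in 16 of 21 and higher in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 5.0e-05; adjusted p = 0.329 with an estimated correlation). Nodal signalling genes were lower in 15 of 20 and higher in 0 (16 and 0 adjusted over the list alone; camera adjusted p = 1.2e-06; adjusted p = 0.252 with an estimated correlation). Ribosomal protein genes were lower in 27 of 74 and higher in 2 (28 and 3 adjusted over the list alone; camera adjusted p = 0.0152; adjusted p = 0.715 with an estimated correlation). Without WT 4 hpf replicate 1 they were lower in 5 and higher in 12 with a median of 0.07, and without pabpc1a MO replicate 2 the camera adjusted p was 0.235.

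At 6 hpf fewer genes differed in pabpc1a MO embryos. DAZL was at 14.0 ± 2.26 against 5.31 ± 0.418 CPM, and PAN2, the catalytic subunit gene of a deadenylase, at 83.4 ± 1.80 against 33.2 ± 1.44 CPM. NSUN5 was at 13.5 ± 0.560 against 42.4 ± 9.91 CPM, apobb.1 at -2.73 and KRTCAP2 at -1.48, while ABHD8 was higher at 11.2 against 0.702 CPM and vcam1b at 13.5 against 1.14 CPM (edgeR adjusted p = 8.39e-06, 0.000731, 0.000145, 0.00106 and 0.000656). The ventral and epidermal genes DLX3 (-3.08) and msx1b (-1.63) were lower, and neither was called without pabpc1a MO replicate 2 (edgeR adjusted p = 0.056 for DLX3 and 0.0784 for msx1b).

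Of 22377 genes, 2050 differed at 6 hpf (1018 higher, 1032 lower, edgeR), 1291 without WT 6 hpf replicate 2 and 1078 without pabpc1a MO replicate 2. A fit of only these 4 libraries called 779. In pabpc1a MO 6 hpf replicate 1, genes that pass 1% in at least 1 library, other than the top gene, took 21.6% of the counts, against 2.06% in replicate 2. BMP signalling genes were lower in 3 of 11 and higher in 0 (camera adjusted p = 2.2e-05; adjusted p = 0.56 with an estimated correlation), with 0 lower by edgeR without pabpc1a MO replicate 2, where the camera adjusted p was 0.00316. Ribosomal protein genes were higher in 8 of 74 and lower in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 2.1e-07; adjusted p = 0.958 with an estimated correlation). Without pabpc1a MO replicate 1 their camera adjusted p was 0.0431. Oocyte mRNAs were higher in 7 of 26 and lower in 0 (9 and 0 adjusted over the list alone; camera adjusted p = 0.0018; adjusted p = 0.64 with an estimated correlation), with 1 higher without WT 6 hpf replicate 2 and a camera adjusted p of 0.0812 without pabpc1a MO replicate 2. Cell cycle genes were higher in 8 of 32 and lower in 1 (11 and 2 adjusted over the list alone), with 1 higher without pabpc1a MO replicate 2, and the camera adjusted p of 0.0156 became 0.408 without WT 6 hpf replicate 2 (adjusted p = 0.64 with an estimated correlation).

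**Figure D4:**
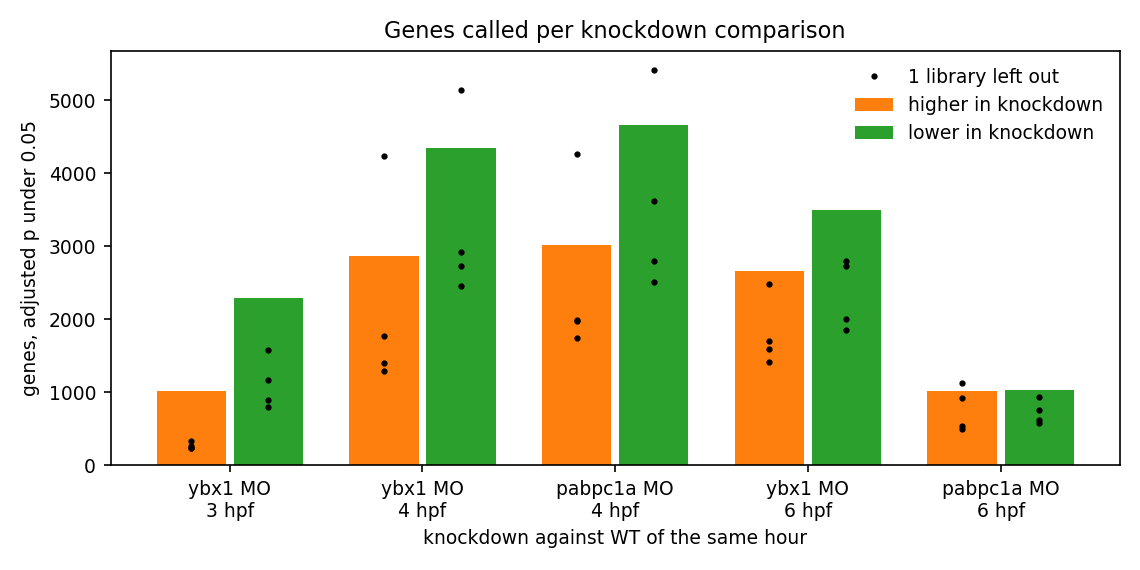
Number of genes called higher (orange) or lower (green) at an edgeR adjusted p under 0.05 in each knockdown against WT of the same hour, with a black point for each count with 1 library left out. The bars are 1020 and 2291 for ybx1 MO at 3 hpf, 2869 and 4338 for ybx1 MO at 4 hpf, 3018 and 4665 for pabpc1a MO at 4 hpf, 2658 and 3492 for ybx1 MO at 6 hpf, and 1018 and 1032 for pabpc1a MO at 6 hpf.

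The knockdowns shared many genes at 4 hpf and fewer at 6 hpf. Without the WT 4 hpf, pabpc1a MO 4 hpf and pabpc1a MO 6 hpf libraries of replicate 1 the shared calls went from 4260 to 1761 at 4 hpf and from 778 to 1249 at 6 hpf. With all libraries, at 4 hpf 1364 genes were higher in both and 2896 lower in both, where independent lists of these sizes give 387 and 904, and 157 went in opposite directions. Across genes the log2 fold changes correlated with Pearson's r = 0.771, against 0.498 in 20 simulations of unchanged groups sharing drawn WT libraries. Their covariance was 2.22 against a simulated 0.173, a difference of 2.05. At 6 hpf 386 were higher in both and 392 lower in both, against 121 and 161 for independent lists, 218 were opposite, and the covariance was 0.618 against a simulated 0.236, a difference of 0.382. The correlation at 6 hpf was no higher than in the simulations, with Pearson's r = 0.445 across genes against a simulated 0.506. Unchanged groups that share a control already give an r of this size, and changes in a single knockdown can lower it. This r therefore cannot show whether effects were shared at 6 hpf. The simulations gave 0 shared calls. The simulations used the spread shared by all poly(A) libraries, while the WT pair at 4 hpf had 5203 genes at least 2-fold apart. They may thus understate what the shared WT libraries give. Genes are not independent replicates, and part of each excess may come from the shared WT libraries, which were not split between the knockdowns. Over the 3 stages of ybx1 MO, 276 genes were higher at each and 424 lower at each.

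Tested against each other at 4 hpf, the knockdowns differed in some ribosomal protein and egg mRNAs. RPL29 was higher in ybx1 MO than in pabpc1a MO (2.92) and RPL21 lower (-1.65). The mitotic kinase mRNAs AURKB (-2.41), aurka (-1.80) and plk1 (-1.12), the egg mRNAs ZAR1L (-1.72) and DAZL (-0.71) and the ribosome assembly gene PNO1 (-3.08) were lower in ybx1 MO. The cell cycle list of 32 genes that holds the kinases had a median of 0.13 in this comparison. At 6 hpf NSUN5 (2.97), APOB (6.97), lhx1a (1.62), CCNA1 (1.29) and HSP90B1 (1.21) were higher in ybx1 MO, and apoa1a (-3.81) and PAN2 (-1.21) lower. Of 22377 genes 3754 differed at 4 hpf (1780 higher and 1974 lower in ybx1 MO, edgeR), 2164, 1757 and 1577 without ybx1 MO replicate 1, ybx1 MO replicate 2 or pabpc1a MO replicate 1, and 6220 at 6 hpf (2758 and 3462), 3488 and 3565 without ybx1 MO replicate 1 or 2. At 4 hpf the maternal declining class was lower in ybx1 MO by a median of -0.30, with 174 genes higher and 925 lower (camera adjusted p = 8.8e-12; adjusted p = 0.295 with an estimated correlation). Ribosomal protein genes had 26 of 74 lower and 4 higher (38 and 4 adjusted over the list alone; camera adjusted p = 1.6e-06; adjusted p = 0.884 with an estimated correlation), with 9 lower without ybx1 MO replicate 2 or pabpc1a MO replicate 1. Of 26 oocyte mRNAs 8 were lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.012; adjusted p = 0.695 with an estimated correlation), and of 15 germ plasm genes 5 and 1 (camera adjusted p = 0.436; adjusted p = 0.884 with an estimated correlation). The early zygotic list had a median of 0.81 with 1 of 23 higher, and 11 without pabpc1a MO replicate 2 (camera adjusted p = 0.0182; adjusted p = 0.884 with an estimated correlation). At 6 hpf no list passed the camera test.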

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

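In this part the tests that leave out WT 4 hpf replicate 1 and both tests of the difference between the WT libraries at 4 hpf were chosen after the result was seen. The comparison with interpolated WT and the refit without the genes over 1% of a library were added after the knockdown results were seen. Their bounds were set before their own values were known. The effects of the knockdowns differed between stages when the difference itself was tested.

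From 3 to 4 hpf the effect of ybx1 MO on early zygotic mRNAs became smaller and that on the transcription-dependent class as a whole larger. The early zygotic list had a median interaction of 3.88, with 8 of 23 higher and 0 lower (camera adjusted p = 0.000299; adjusted p = 0.556 with an estimated correlation; 13 and 3 adjusted over the list alone). Without ybx1 MO 3 hpf replicate 2 only 2 were higher. Against WT of the same hour the list had a median of -5.12 at 3 hpf and still of -1.63 at 4 hpf in ybx1 MO. Its member klf17 was at 132 CPM in ybx1 MO at 4 hpf and at 126 CPM in WT. For the transcription-dependent class the median was -0.76, or -0.99 with groups at or under 3 counts set to 3 counts (camera adjusted p = 5.99e-11; adjusted p = 0.345 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.66 (camera adjusted p = 6.98e-28; adjusted p = 0.51 with an estimated correlation). Of these 8 of 74 were lower, and 68 without WT 4 hpf replicate 2. By edgeR 458 genes were called (172 higher, 286 lower), from 126 without ybx1 MO 3 hpf replicate 1 to 3623 without WT 4 hpf replicate 2.

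From 4 to 6 hpf the ybx1 MO effect on zygotic mRNAs went back towards WT, while apobb.1 and apoa1a were lower than in WT at 6 hpf only. In WT apoa1a was still very low at 4 hpf, so the size of its interaction rests on small counts. The envoplakin gene evpla had an interaction of 9.54, apobb.1 of -6.70 and apoa1a of -5.70 (edgeR adjusted p = 0.00149, 4.85e-05 and 7.91e-05). The medians were 1.98 for the transcription-dependent class, 0.80 for ribosomal protein genes and 2.69 for Nodal signalling genes (camera adjusted p = 1.26e-23, 5.52e-15 and 1.52e-08; adjusted p = 0.359 for each with an estimated correlation). With groups at or under 3 counts set to 3 counts, the class median was 1.85 and that of Nodal signalling genes 2.40. Of the Nodal signalling genes 15 of 20 were higher, and 9 without ybx1 MO 4 hpf replicate 1. The yolk syncytial layer list, which holds apobb.1 and apoa1a, had a median of 3.035 with 4 of 11 higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.0338; adjusted p = 0.509 with an estimated correlation), and 2 higher without ybx1 MO 4 hpf replicate 1. By edgeR 5898 genes were called (3307 higher, 2591 lower), and 3803 without ybx1 MO 4 hpf replicate 1.

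For pabpc1a MO the effect on zygotic mRNAs also became smaller from 4 to 6 hpf. The interactions of the knockdowns share the WT libraries and were not tested against each other. The medians were 2.40 for the transcription-dependent class, 2.82 for early zygotic transcripts and 2.88 for Nodal signalling genes (camera adjusted p = 3.92e-34, 3.33e-09 and 2.72e-07; adjusted p = 0.179, 0.234 and 0.234 with an estimated correlation). With groups at or under 3 counts set to 3 counts the class median was 2.24 and the Nodal median 2.73. Of the early zygotic list 13 of 23 were higher, and 7 without WT 4 hpf replicate 1. The ventral gene msx1b had an interaction of -3.52 and si:ch211-246m6.5 of -4.32 (edgeR adjusted p = 0.000234 and 0.000401). By edgeR 5109 genes were called (3158 higher, 1951 lower), 7669 without WT 4 hpf replicate 2 and 3014 without pabpc1a MO 4 hpf replicate 1.

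Embryos at an earlier stage could show the same loss of transcription-dependent mRNAs, so each knockdown was also compared with WT interpolated by least squares to the stage nearest in this class (2.1, 3.22 and 3.02 hpf, with class medians of -0.37, -0.09 and -0.05 left). Among genes outside the class, the calls for ybx1 MO at 3 hpf reached 121% of the same-hour calls (117% against WT at 2 hpf, with a class median of -0.09). For ybx1 MO at 4 hpf they reached 63.6% (57.3% against WT at 3 hpf, with a class median of 0.39), which is nearer the bound set. Both argue against an earlier stage as the only difference, more weakly at 4 hpf. For pabpc1a MO at 4 hpf they reached 21.6% (20.9% against WT at 3 hpf), which leaves an earlier stage possible. A few genes taking most of the counts is argued against by class medians of -1.99 (ybx1 MO) and -2.33 (pabpc1a MO) at 4 hpf without the genes over 1% of a library. Scaling by trimmed mean of M values already limits the pull of such genes, and ybx1 MO at 3 hpf was not tested this way. A WT library further along is argued against as the whole cause by medians of -1.49 and -1.82 without WT 4 hpf replicate 1. A slower development caused by a knockdown and one caused by injection stay open, since no injected control is named, and poly(A) selection also responds to tail length, which was not measured. Among the poly(A) libraries only those of ybx1 MO came with HTSeq's summary lines, so they may have been handled apart. A difference in handling could also give calls outside the class and cannot be told apart from ybx1 MO here.

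The WT libraries at 4 hpf differed from each other, with 5203 genes at least 2-fold apart. Across genes, replicate 1 minus replicate 2 correlated with WT at 6 minus 3 hpf (Pearson's r = 0.453, Spearman's rho = 0.492), against -0.236 to 0.175 in the other groups not used for that difference, and genes are not independent replicates. Embryos of replicate 1 further along in development is a candidate explanation that this value, between the bounds set, leaves open. A few genes taking most of the counts is argued against by a difference of 0.722 percentage points in the share of genes that pass 1% in at least 1 library.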

How the results depend on the processing

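Refits without the genes over 1% of a library and without 3 doubted libraries (WT 4 hpf replicate 1, pabpc1a MO 4 hpf replicate 1 and pabpc1a MO 6 hpf replicate 1) were chosen after the results were seen. The cause of the changes below was not tested. For the named genes 1772 of 1807 recomputed values kept their call and direction. These genes were chosen mainly among those whose call held under the alternatives, so this count does not measure how stable the calls are. Of 202 recomputed counts of calls 156 stayed within 1.5 times the count reported, and of 144 recomputed class medians 123 kept their direction and side of the threshold. Scaling by spike-ins was not run.

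A fit of only the libraries of the groups compared called 4562 genes in WT at 3 against 2 hpf, 0 in WT at 4 against 3 hpf (5035 at an unadjusted p under 0.05 by edgeR, and 6813 called by DESeq2 in the full fit). It called 7251 and 1009 for ybx1 MO at 3 and 4 hpf, 0 for pabpc1a MO at 4 hpf (5949 unadjusted by edgeR, 8339 called by DESeq2 in the full fit) and 779 at 6 hpf. In the interactions it called 77 and 3477 for ybx1 MO (4 against 3 and 6 against 4 hpf) and 1340 for pabpc1a MO. DESeq2 called 1997 in WT at 3 against 2 hpf and 1407 in the first interaction.

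Without the 3 doubted libraries 4022 genes were called in WT at 4 against 3 hpf, 3209 for pabpc1a MO at 4 hpf and 2704 in its interaction, with 1761 and 1249 calls shared by the knockdowns at 4 and 6 hpf. With a log2 fold change of at least 1 in size the shared calls were 2735 and 310.

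Leaving out each library in turn, where a lone sample is assumed to vary like the other groups, gave 183 to 716 calls for WT at 3 against 2 hpf, 2826 to 8718 at 4 against 3 hpf. It gave 1036 to 1911, 3852 to 9383 and 3427 to 5278 for ybx1 MO at 3, 4 and 6 hpf, 4248 to 9662 and 1078 to 2065 for pabpc1a MO at 4 and 6 hpf. Between the knockdowns it gave 1577 to 2559 and 3488 to 4667 at 4 and 6 hpf, and 126 to 3623, 3803 to 8042 and 3014 to 7669 in the interactions.

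With an estimated correlation the camera test lost the class medians of -0.96 (ybx1 MO, 3 hpf, transcription-dependent), -1.99, 0.09 and 0.16 (ybx1 MO, 4 hpf, transcription-dependent, declining and stable) and -2.36, 0.38 and 0.13 (pabpc1a MO, 4 hpf). The declining class of ybx1 MO at 4 hpf (0.08919) was also lost with the stricter class threshold (0.07057), with a replicate block (0.08992), without the 3 doubted libraries (0.004909), without WT 4 hpf replicate 1 (0.00528) and without ybx1 MO replicate 1 (0.06788). Without WT 4 hpf replicate 2 it was 0.2465. Replicate numbers showed little pairing, with a median r of 0.00659 over 45 pairs of poly(A) groups. The values ran from -0.119 (WT and pabpc1a MO at 4 hpf) to 0.195 (WT at 3 hpf and pabpc1a MO at 4 hpf).

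Medians near 0 changed sign. These were in ybx1 MO at 3 hpf the declining class (0.02438 without the genes over 1%) and the stable class (0.07104 without them, 0.02489 with median-of-ratios size factors). In pabpc1a MO at 6 hpf they were the declining class (-0.008106 and -0.00219 without WT 6 hpf or pabpc1a MO replicate 2) and the stable class (0.008241 with size factors, 0.03269 without the 3 doubted libraries, 0.02888 and 0.0351 without WT 6 hpf or pabpc1a MO replicate 1). Their signs were kept at 0.08891 for the declining class without WT 6 hpf replicate 1 and at -0.08844 for the stable class without pabpc1a MO replicate 2.

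The log2 fold change of pabpc1a in pabpc1a MO vs WT at 6 hpf changed sign to 0.08811 without WT 6 hpf replicate 2, and was at -0.4433 without WT 6 hpf replicate 1.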

Other observations

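No test in this part was chosen after its own result was seen, though the tests on vitellogenin followed from seeing vitellogenin. In the amanitin embryos vitellogenin mRNAs, which encode yolk precursors made in the adult liver, appeared at 6 hpf, all but vtg8 with 6 counts at 6 hpf and 4 at 4 hpf. vtg1 was at 411 ± 20.8 CPM and vtg2 at 138 ± 8.01 CPM, higher than at 4 hpf by 10.78 and 11.05 on the log2 scale (edgeR adjusted p = 7.14e-26 and 3.11e-23). The list of ovary, liver and egg yolk mRNAs had 9 of 10 genes higher and 1 lower, and the same adjusted over the list alone. Its median was 9.38, or 8.57 with groups at or under 3 counts set to 3 counts (camera adjusted p = 0.0038; adjusted p = 0.264 with an estimated correlation).

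RNA of adult liver mixed into these samples is a candidate explanation. Of 35 other liver mRNAs 21 were tested, and 52.4% of these were called and at least 4-fold higher at 6 than at 4 hpf, against 3.84% of all tested genes, but 2 were lower. The levels were low, with a median of 0.488 CPM and at most 1.37 CPM among the 11 that were higher, and 8 of the 21 reached 1 CPM in WT poly(A) libraries at 6 hpf, so this stays open. Transcription that continued in spite of amanitin and follows the WT program is argued against for vtg1 mRNA with a poly(A) tail. Its CPM in the poly(A) WT libraries at 6 hpf was 0.0353% of that in the rRNA-depleted amanitin libraries. The values were 0.113 against 319 CPM when scaled by library totals alone, where the 411 CPM above also uses edgeR's scaling. The series has no rRNA-depleted WT libraries at 6 hpf, so RNA without a tail was not compared. For the other 819 mRNAs at least 4-fold higher at 6 than at 4 hpf, 35.7% of the 603 tested in the poly(A) libraries were called higher in WT over the same hours, against 26.9% of all genes (Fisher's exact test, p = 1.82e-06). That test treats genes as independent, which they are not. The value of 35.7% leaves continued transcription open.

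Interferon and innate immune genes at 4 hpf were lower in 4 of 10 and higher in 0 in ybx1 MO (5 and 0 adjusted over the list alone; camera adjusted p = 0.0358; adjusted p = 0.321 with an estimated correlation). The camera adjusted p was 0.0502 without ybx1 MO replicate 1. Heat shock and unfolded protein response genes went both ways in ybx1 MO at 4 hpf, 5 of 20 higher and 6 lower (the same adjusted over the list alone). They had a median of -0.03, a mean of -0.62 and camera giving the direction as up (camera adjusted p = 0.768; adjusted p = 0.838 with an estimated correlation). RNA methylation and cold shock protein genes were higher in 7 of 26 and lower in 3 in ybx1 MO at 6 hpf (9 and 3 adjusted over the list alone; camera adjusted p = 0.117; adjusted p = 0.768 with an estimated correlation). Genome activation transcription factors were lower in 5 of 11 and higher in 1 in pabpc1a MO at 4 hpf (7 and 1 adjusted over the list alone; camera adjusted p = 0.06; adjusted p = 0.252 with an estimated correlation). Genes of later differentiated tissues were lower in 2 of 9 and higher in 1 in the same comparison (the same adjusted over the list alone; camera adjusted p = 0.293; adjusted p = 0.336 with an estimated correlation).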
